A study of Mus musculus with 6 samples.

How the data were processed

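The data are RNA sequencing libraries of mouse primary neurons, 3 infected with an AAV for miR-9-3p and 3 with a control AAV, grouped by the treatment labels and titles. The labels disagree on the control vector (scramble or mCherry), and the values were used as the labels group them. The authors deposited 1 table of FPKM values, 1 column per library, per the file headers. HISAT2 (version not given in the sources used here), Cufflinks 2.2.1 and the mouse build mm10 are named in the submitters' processing notes, with no role or order. The annotation, strand setting, trimming and filters were not given in the sources used here. FPKM divides by gene length and library total, so a transcript that takes a large share of 1 library lowers all its other values, and no scaling between libraries beyond this was stated.

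Gene symbols, positions and exon lengths came from GENCODE M21, which annotates GRCm38 (mm10). Of 55416 identifiers, 52083 matched, and the 3333 without a symbol held at most 1.23% of a library's FPKM sum. Low values of a gene were whole multiples of 1 step that depended on its exon length. Dividing by this step gave whole reads, within 0.01, for between 98.05% and 98.14% of the values above 0 in a library. The depths so recovered were 16001205 to 17936453 reads per library. No pair of libraries agreed within sampling noise, and each was counted as 1 replicate. Lung RNA, described below, differed between the libraries, so this check cannot tell separate cultures from technical repeats. The closest pair was miR-9-3p AAV libraries 2 and 3 (Pearson r 0.988). The depth sets the precision of low genes: the counts behind Bdnf ran from 177 to 460 reads.

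FPKM values were tested on the scale log2(FPKM + 1), which understates the fold changes of low genes, with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend, no covariates), on genes with at least 1 FPKM in at least 3 libraries (14229 genes). Genes with a Benjamini-Hochberg adjusted p under 0.05 are called higher or lower. Gene lists (30, written before the data were examined) were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry, with adjustment over the 29 lists with at least 3 tested genes. For each list the members passing are given over all genes tested and adjusted over the list alone. The rule for the named genes was also set before the data were examined. Among called genes whose groups do not overlap, with a mean of at least 2 FPKM in a group and a symbol that is not a placeholder, it takes the 12 largest log2 fold changes in each direction and the 6 highest means. It adds all reported targets and, in each list, up to 4 called members with the largest change, or, with 0 called, the 2 with the lowest p. Some genes that the rule takes are not reported here. The lung genes, Mir9 loci and Mir9-3hg fall outside it; the lung genes were chosen after their values were seen.

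For seed matches, 3′ UTR sequences were taken from the coding ends and exons of GENCODE coding transcripts, for genes with at least 30 bases. Each gene was represented by its longest annotated 3′ UTR, and shorter forms were not examined. A match is the complement of microRNA positions 2 to 8, or of 2 to 7 followed by A. The coefficient of having a match, in a linear model of the log2 fold change on log2 UTR length and A+T share, was ranked among 1000 control heptamers found in a number of genes within 20% of the seed's. The limma and seed steps were tested on simulated data. With 200 of 14229 genes changed in the miR-9-3p AAV comparison, limma recovered 79% of those changed by a fold of 2 and 19% of those changed by a fold of 1.5, and 6 of 104 calls were false. The genes were simulated independently of each other, without variation that genes share, such as that of lung RNA. These rates need not hold for the real libraries. A simulated seed effect of -0.2 over 12194 genes was recovered as -0.215. With no effect simulated the coefficient was -0.015, with a one-sided p of its rank of 0.058. Effects as small as the seed coefficients reported below were not simulated.

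Alternatives fixed before the data were examined were the replicate number as a block, a pseudocount of 0.1, no filter and a filter of 5 FPKM, quantile normalization, median-of-ratios size factors, no intensity trend, array quality weights, leaving out each library, a log2 fold change of at least 1, 8-base matches and a seed model without covariates. Added after seeing the data were the lung level as a covariate, leaving out the library of each group with the highest lung level, the lung set as a batch term, removal of each library's trend on exon length or GC share, voom on the recovered reads, and control heptamers of the seed's own bases. The ranking of all heptamers, the miR-124 match and the miR-9-5p and miR-9-3p tests within the lung sets were also added, after the miR-9-5p result was seen. The lung level is the median, over the genes of an alveolar type 2 list, of the log2 ratio to the mean of the libraries. It belongs to 6 lung lists (airway secretory, alveolar type 2, alveolar type 1, endothelium, atrial-type heart muscle, macrophages) written after the first lung genes were noticed. The lung sets divide libraries at a Bpifa1 to Scgb1a1 ratio of 0.5%. Count-based tools were not run as the main test, since the deposited values are not counts. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served the annotation, seed and figure steps.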

Results

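RNA was sequenced from mouse primary neurons, which are neurons taken from brain tissue and kept in culture, after infection with an adeno-associated virus (AAV). In 3 libraries the virus carried miR-9-3p behind the synapsin promoter, which is active in neurons. The other 3 libraries came from a control virus, which the sample titles and treatment labels call a scramble vector and the extraction protocol and design text call an mCherry vector. Both groups are called here as the labels group them, miR-9-3p AAV and control AAV. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical. The deposited table gives FPKM, fragments per kilobase of transcript scaled to the library total, for 55416 mouse genes. Depth recovered from the steps between low values was 16001205 reads in control AAV library 1, 17936453 in library 2 and 17745014 in library 3. It was 17174916, 16953251 and 16965306 reads in miR-9-3p AAV libraries 1, 2 and 3.

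The comparison of the vectors asks which transcripts change in neurons that receive miR-9-3p, a microRNA strand that silences messenger RNAs with matching 3′ untranslated regions (UTRs). Of 34 tested voltage-gated channel genes 10 were higher and 0 lower in miR-9-3p AAV, and of 28 genes of the unfolded protein and ATF4 response 0 were higher and 7 lower. Among single genes Camk4, a calcium/calmodulin-dependent kinase, went from 5.88 ± 0.151 to 14.6 ± 0.772 FPKM (SD, n = 3 per group), a log2 fold change of 1.18 with a standard error (SE) of 0.08 and a limma adjusted p of 0.017. Slc25a18 (ENSMUSG00000004902, chromosome 6, 120773578 to 120794336), a mitochondrial glutamate carrier, went from 66.6 ± 5.44 to 17.2 ± 2.22 FPKM (SD, n = 3), a log2 fold change of -1.90 (SE 0.12, limma adjusted p = 0.017). Of 14229 genes tested, 554 were higher and 341 lower in miR-9-3p AAV at a Benjamini-Hochberg limma adjusted p under 0.05, and 465 and 313 of these were protein coding. In each of these genes the values of the groups did not overlap. Such separation held for 34.9% of tested genes. Chance gives 10% on average over the divisions of 6 libraries, but genes vary together, so a single division can lie far from this. The counts changed with the libraries in the fit. They were 0 and 0 in limma without control AAV library 1 or 2 or without miR-9-3p AAV library 1, 2 or 3, where between 2646 and 3588 genes had an unadjusted p under 0.05, and 460 and 272 without control AAV library 3. They were 792 and 885 without control AAV library 3 and miR-9-3p AAV library 1, which had the most lung RNA (described below) in their groups. Log2 fold changes rose with exon length (Spearman rho 0.27 across the tested genes, which are not independent replicates), and the counts were 278 and 209 with each library's trend on length removed.

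**Figure D1:**
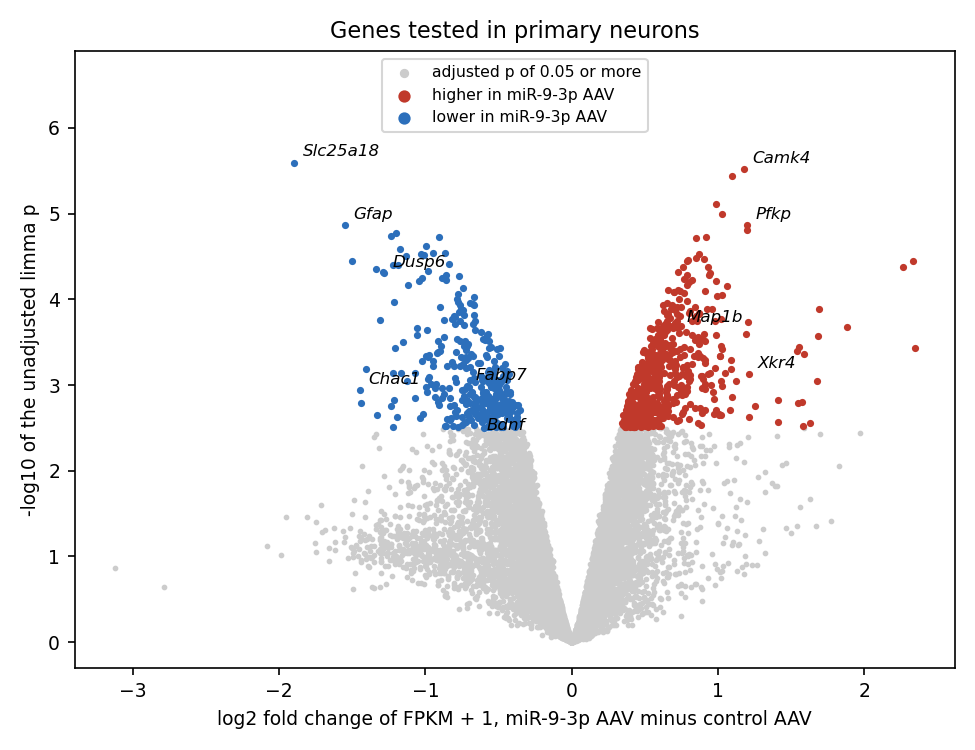
Each point is 1 of 14229 genes, with the log2 fold change of FPKM + 1 (miR-9-3p AAV minus control AAV) on the x axis and the -log10 of the unadjusted p on the y axis. The 554 genes called higher are red and the 341 called lower are blue, and Bdnf lies just under the called genes.

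Among the named increases, Xkr4 rose from 9.29 ± 2.75 to 22.4 ± 2.34 FPKM (SD, n = 3; log2 fold change 1.21, limma adjusted p = 0.0299). Pfkp, an isoform of the glycolytic enzyme phosphofructokinase, rose from 18.3 ± 1.89 to 43.3 ± 1.89 FPKM, and Plxnc1, a semaphorin receptor, from 7.08 ± 0.343 to 16.2 ± 0.129 FPKM. The potassium channel gene Kcna3 rose by 1.08 on the log2 scale, the calcium-binding calneuron gene Caln1 by 1.06 and the GABA-A receptor subunit gene Gabrb2 by 1.03. Slc16a6, of the monocarboxylate transporter family, rose by 1.20, Klhl34 by 1.09 and Nktr by 1.05. Far1os, with a log2 fold change of 1.19, is antisense to its neighbour and the strand setting was not given in the sources used here, so its value is uncertain. The mitochondrial transfer RNA gene mt-Ta was listed at 0 in the control libraries and at 1.69, 4.27 and 2.56 FPKM in the miR-9-3p libraries. It is 69 bases long and is not well measured by such libraries. Among the most abundant called genes, Map1b rose from 125 ± 7.38 to 207 ± 10.5 FPKM, the long noncoding RNA Meg3 from 118 ± 13.1 to 186 ± 13.2 FPKM and Enc1 from 97.45 ± 12.5 to 181 ± 11.3 FPKM (SD, n = 3).

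Among the named decreases, Gfap, the intermediate filament gene of astrocytes, fell from 98.1 ± 10.04 to 32.9 ± 4.44 FPKM (SD, n = 3; log2 fold change -1.55, limma adjusted p = 0.017). Chac1, which degrades glutathione and is a target of the transcription factor ATF4, fell from 21.7 ± 7.06 to 7.08 ± 1.18 FPKM, and Trib3, another ATF4 target, from 3.44 ± 0.946 to 0.765 ± 0.0939 FPKM. Dusp6 and Spry1, both antagonists of ERK signalling, had log2 fold changes of -1.28 and -1.22. Cartpt, which encodes a neuropeptide precursor, had a log2 fold change of -1.41. The values were -1.50 for Glycam1, -1.34 for the peroxidase gene Lpo, -1.23 for Scrg1 and -1.22 for Dhrs4. B2m, the light chain of MHC class I, went from 108 ± 38.0 to 44.8 ± 9.13 FPKM with a limma adjusted p of 0.0498. Its log2 fold change moved from -1.23 to -0.72 with the lung RNA level described next as a covariate (adjusted p = 0.025), while its adjusted p ranged from 0.00279 to 0.261 over the alternatives. Among abundant genes, Fabp7, a fatty acid binding protein of radial glia and astrocytes, fell from 825 ± 81.9 to 500 ± 20.3 FPKM. Laptm4a and Eif1 had log2 fold changes of -0.50 and -0.52.

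**Figure D2:**
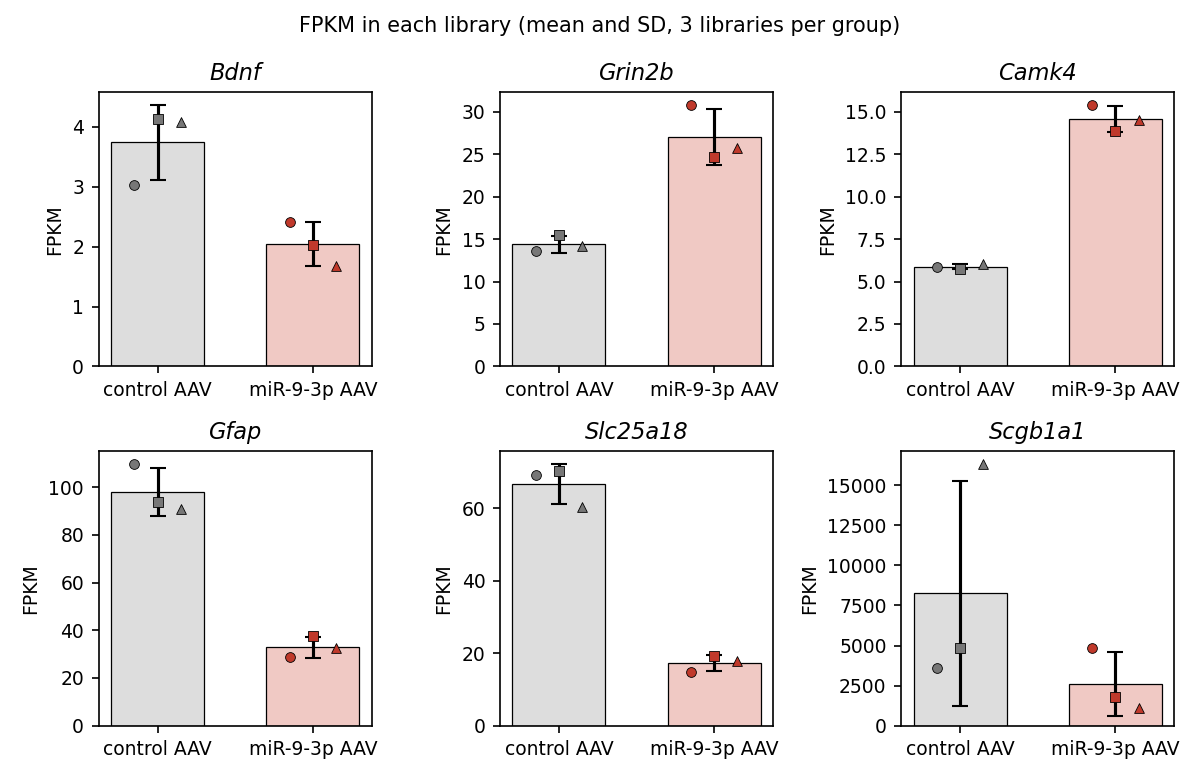
FPKM of 6 genes in each library, with control AAV in grey and miR-9-3p AAV in red. Bars are means, error bars are SDs (n = 3 per group), and the circle, square and triangle are libraries 1, 2 and 3. Gfap and Slc25a18 separate the groups, while the lung gene Scgb1a1 runs from 1131 to 16310 FPKM with overlap between them.

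Transcripts of lung cells were abundant in all 6 libraries and varied within each group. Scgb1a1, the secretoglobin of airway club cells, stood at 3589, 4871 and 16310 FPKM in control AAV libraries 1, 2 and 3 and at 4871, 1791 and 1131 FPKM in miR-9-3p AAV libraries 1, 2 and 3. Sftpc, a surfactant gene of alveolar type 2 cells, stood at 831, 1335 and 4571 FPKM and at 1371, 515 and 401 FPKM. The median level of alveolar type 2 genes, called the lung level here, was 2.41, 3.30 and 10.9 times the lowest library in control AAV and 3.26, 1.19 and 1 times in miR-9-3p AAV. Its group difference of -1.50 (log2) was smaller than its range of 2.18 within control AAV, with an exact permutation p of 0.2 (two-sided; 3 against 3 libraries cannot give less than 0.1). Bpifa1, another airway gene, stood at 0.966%, 0.959% and 0.939% of Scgb1a1 in control AAV libraries 2 and 3 and miR-9-3p AAV library 1. It stood at 0.029% in control AAV library 1 and was listed at 0 in miR-9-3p AAV libraries 2 and 3. The libraries thus formed 2 sets of 3 with both groups in each. Within these sets the group differences of the tested genes had a Pearson r of 0.671 and a Spearman rho of 0.744 across genes, which are not independent replicates, and 80.3% had the same sign. Gfap had log2 differences of -1.65 and -1.62 within the sets, Slc25a18 -2.07 and -1.85, and Camk4 1.25 and 1.15. With the lung level as a covariate, chosen after seeing the data, 1754 genes were higher and 2309 lower, among them 549 and 331 of the calls above.

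Of 34 tested voltage-gated channel genes, 10 were higher and 0 lower over all genes tested, and 17 were higher and 0 lower adjusted over the list alone. Examples were the calcium channel genes Cacna1e (log2 fold change 0.94), Cacna1d (0.76) and Cacna1b (0.72) and the potassium channel gene Kcnq3 (0.87). The list median was 0.37, with a camera adjusted p of 5.2e-07 and an adjusted p = 0.275 with an estimated correlation. Of 26 glutamate receptor genes, 5 were higher and 0 lower, and 12 and 0 adjusted over the list alone. The NMDA receptor subunit gene Grin2b rose from 14.4 ± 1.004 to 27.0 ± 3.29 FPKM (SD, n = 3), Grm3 by 0.71 on the log2 scale and Gria1 by 0.59. This list had a median of 0.32 and a camera adjusted p of 2.23e-05, with an adjusted p = 0.297 with an estimated correlation. Of 31 postsynaptic scaffold and adhesion genes, 4 were higher and 0 lower, and 13 and 1 adjusted over the list alone, with increases of 0.65 for Homer2, 0.65 for Lrrc7, 0.56 for Dlg2 and 0.51 for Cnksr2 (median 0.30, camera adjusted p = 5.11e-05, adjusted p = 0.357 with an estimated correlation). The rotation test fry, which asks whether the genes of a list move one way on balance, gave adjusted p-values of 0.0129, 0.0353 and 0.0654 for these lists. With the lung level as a covariate the channel list kept its call (median 0.35, camera adjusted p = 0.00123), and the glutamate receptor list (0.24, camera adjusted p = 0.147) and postsynaptic list (0.09, camera adjusted p = 0.257) did not.

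Of 33 synaptic vesicle and release genes, 5 were higher and 0 lower, and 10 and 0 adjusted over the list alone. Sv2b rose by 0.85 on the log2 scale and the active zone genes Erc2, Unc13b and Pclo by 0.61, 0.56 and 0.49. The median was 0.24 (camera adjusted p = 0.000169, adjusted p = 0.528 with an estimated correlation). Of 31 genes of the axon and dendrite cytoskeleton, 6 were higher and 0 lower, and 9 and 0 adjusted over the list alone. Dcx, the microtubule protein of migrating and young neurons, rose by 0.80, Map1b by 0.73, Ank3 by 0.65 and Map2 by 0.65 (median 0.21, camera adjusted p = 0.000103, adjusted p = 0.528 with an estimated correlation). Both list calls ended with the lung level as a covariate, where the medians were -0.04 and -0.12 (camera adjusted p = 0.926 for each), and fry gave adjusted p-values of 0.156 and 0.162 with the main settings. Of 26 GABA synapse genes 1, Gabrb2, was higher and 0 were lower, and 3 and 0 adjusted over the list alone (median 0.06, camera adjusted p = 0.059). This list passed camera without control AAV library 1 (0.0255) or 2 (0.0314) or miR-9-3p AAV library 3 (0.0268) and with voom (0.0453), and had a fry adjusted p = 0.204. Of 13 neurotrophin and receptor genes 1 was higher and 0 lower, and 2 and 1 adjusted over the list alone. That gene was Ntrk3, the receptor of neurotrophin-3, with a log2 fold change of 0.55. The list had a camera adjusted p of 0.0499, an adjusted p = 0.306 with an estimated correlation, a fry adjusted p = 0.0296, and 0.336 by camera with the lung level as a covariate. Its call also ended without control AAV library 2 (0.0667) or 3 (0.0885) and without miR-9-3p AAV library 1 (0.0624), 2 (0.0657) or 3 (0.056). It ended too with the replicate block (0.0559), quantile normalization (0.0818), the lung set as a batch term (0.12), the exon length trend (0.224) or GC trend (0.0596) removed, and without the highest lung library of each group (0.174).

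**Figure D3:**
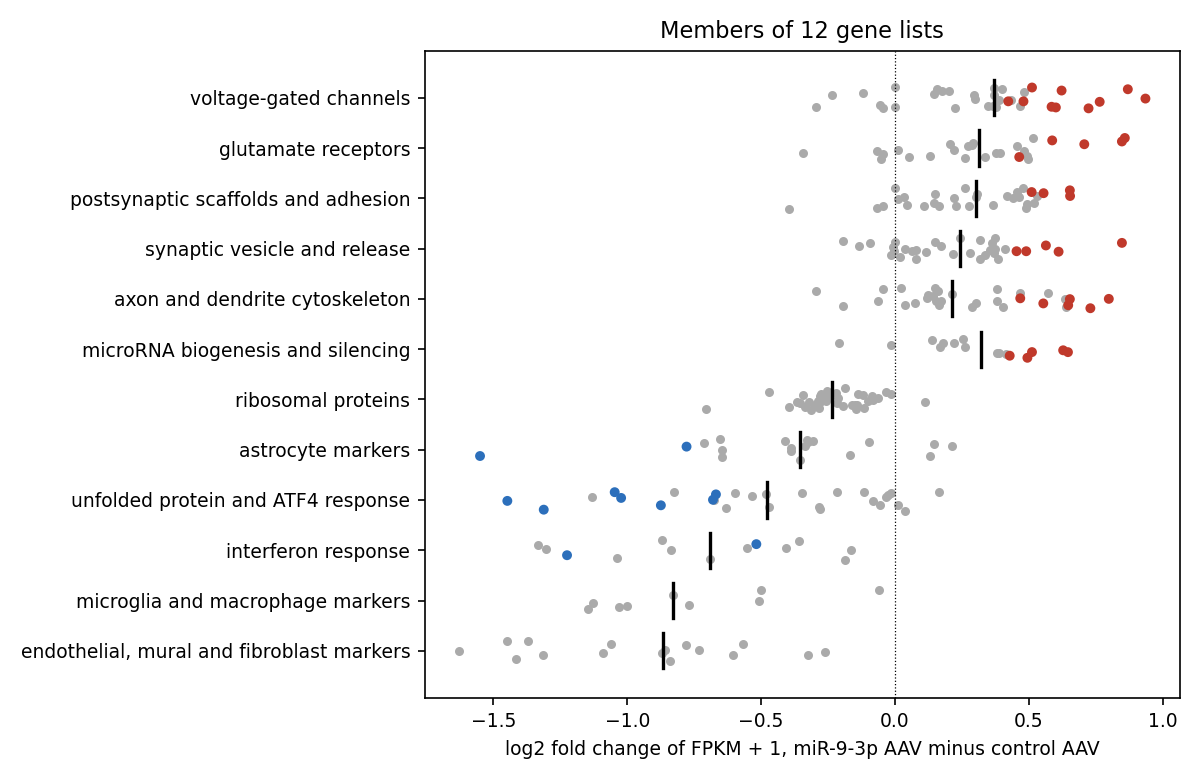
Log2 fold change of FPKM + 1 (x axis, miR-9-3p AAV minus control AAV) of each tested member of 12 gene lists (y axis, with points spread vertically for visibility). Red and blue points passed the adjusted limma threshold, grey points did not, and black bars are list medians, from 0.37 for voltage-gated channels to -0.87 for endothelial, mural and fibroblast markers.

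Of 28 tested genes of the unfolded protein and ATF4 response, 0 were higher and 7 lower, and 0 and 12 adjusted over the list alone. Besides Chac1 and Trib3, the mitochondrial folate enzyme gene Mthfd2 fell from 17.1 ± 2.27 to 7.71 ± 0.327 FPKM and Herpud1, of endoplasmic reticulum protein degradation, from 39.4 ± 6.99 to 18.8 ± 2.63 FPKM (SD, n = 3). The list median was -0.48 (camera adjusted p = 3.21e-06, adjusted p = 0.124 with an estimated correlation, fry adjusted p = 0.00136). Of 19 astrocyte markers, 0 were higher and 2, Gfap and Acsbg1, were lower, and 0 and 9 adjusted over the list alone. Acsbg1, an acyl-CoA synthetase gene, fell from 73.7 ± 12.5 to 42.5 ± 6.72 FPKM. The astrocyte median was -0.36 (camera adjusted p = 0.000204, adjusted p = 0.275 with an estimated correlation, fry adjusted p = 0.0171). With the lung level as a covariate both lists kept their calls, at medians of -0.36 for the stress response and -0.48 for astrocytes. Of 18 oligodendrocyte lineage markers 1 was higher and 1 lower, and 2 and 3 adjusted over the list alone. Pdgfra, a receptor of oligodendrocyte precursors, rose from 12.3 ± 1.38 to 22.75 ± 1.23 FPKM (SD, n = 3; list median -0.29, camera adjusted p = 0.0724). Of 17 neural progenitor markers 0 were higher and 1, Fabp7, was lower, also over the list alone (median -0.31, camera adjusted p = 0.0408, adjusted p = 0.297 with an estimated correlation, fry adjusted p = 0.0613). The progenitor call ended without miR-9-3p AAV library 1 (camera adjusted p = 0.101) and with the GC trend (0.123) or the exon length trend (0.0506) removed. The oligodendrocyte list had a fry adjusted p = 0.204 and passed camera with the lung level as a covariate (0.0095), no filter (0.00577) or quantile normalization (0.0463), without control AAV library 3 (0.0179) and without the highest lung library of each group (0.0303).

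Immune, vascular and blood markers were lower on median but followed the lung level within groups. Of 13 interferon response genes 0 were higher and 2, B2m and Irf9, were lower, and 0 and 3 adjusted over the list alone (median -0.69, camera adjusted p = 0.000169, adjusted p = 0.528 with an estimated correlation). Of 16 endothelial, mural and fibroblast markers, 9 microglia and macrophage markers and 9 inflammatory cytokine and NF-κB genes, 0 passed in either direction. Adjusted over the list alone, 1 inflammatory gene was lower and the counts of the other lists were 0. Their medians were -0.87, -0.83 and -0.67 with camera adjusted p-values of 0.000421, 0.019 and 0.00857, each with an adjusted p = 0.528 with an estimated correlation. By fry the adjusted p-values were 0.14 for the interferon list and 0.229, 0.258 and 0.204 for these 3. Pdgfrb of mural cells had a value of -0.86 (limma adjusted p = 0.0999), Col3a1 -0.87 (0.144), Cd68 -0.51 (0.128), Cd14 -1.15 (0.192), Nfkb2 -0.67 (0.0598) and Vcam1 -0.29 (0.121). Of 5 blood cell genes 0 passed, also over the list alone (median -0.89, camera adjusted p = 0.17), with -0.84 for Hba-a2 and -0.89 for Hbb-bt. Within groups the median slope of these lists on the log2 lung level was 0.34 for interferon, 0.60 for endothelial, 0.66 for microglial, 0.50 for inflammatory and 0.85 for blood genes. With the lung level as a covariate the camera adjusted p-values of the interferon, endothelial, microglial and inflammatory lists were 0.336, 0.904, 0.751 and 0.964. The medians were then -0.23, -0.02, 0.11 and 0.04. The blood list, which did not pass in either fit, had a median of 0.501 with the covariate (camera adjusted p = 0.182). The microglial call also ended without control AAV library 3 (0.127) or miR-9-3p AAV library 3 (0.0684), and the inflammatory call without control AAV library 3 (0.0822). The microglial call ended with the lung set as a batch term (0.1) and with the exon length trend (0.0668) or GC trend (0.0715) removed, the inflammatory call with the lung set as a batch term (0.0582) and at a filter of 5 FPKM (0.0781), and the endothelial call at that filter (0.0561). The blood list passed without control AAV library 1 (0.0151).

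Of 16 genes of microRNA biogenesis and silencing, 5 were higher and 0 lower, and 10 and 0 adjusted over the list alone. They included Dicer1, which cuts microRNA hairpins (5.19 ± 0.714 to 8.52 ± 0.135 FPKM, SD, n = 3), the Argonaute gene Ago2 (log2 fold change 0.49), Tnrc6b (0.51) and Lin28b (0.65). The list median was 0.32 (camera adjusted p = 3.29e-05, adjusted p = 0.232 with an estimated correlation, fry adjusted p = 0.00136), and 0.33 with the lung level as a covariate (camera adjusted p = 0.000507). Of 27 activity-induced genes 0 were higher and 1, Dusp6, was lower, and 3 and 6 adjusted over the list alone (median -0.42, camera adjusted p = 0.016, adjusted p = 0.528 with an estimated correlation, fry adjusted p = 0.204). This call ended with the lung level as a covariate (camera adjusted p = 0.751), without control AAV library 3 (0.0784), with array quality weights (0.0559), with the lung set as a batch term (0.0642) and with the exon length trend (0.0506) or GC trend (0.0691) removed. Of 25 insulin and mTOR signalling genes 2 were higher, among them Grb10 (0.38), and 1 lower, Eif4ebp1 (-0.97), with the same counts over the list alone (median 0.18, camera adjusted p = 0.016, adjusted p = 0.275 with an estimated correlation, fry adjusted p = 0.02). This call too ended with the lung level as a covariate (camera adjusted p = 0.0709), with the exon length trend removed (median 0.036, camera adjusted p = 0.445) and at a filter of 5 FPKM (0.0787). Of 38 ribosomal protein genes 0 passed, also over the list alone, with a median of -0.24 and values of -0.34 for Rps25 and -0.34 for Rps4x (camera adjusted p = 0.000104, adjusted p = 0.528 with an estimated correlation, fry adjusted p = 0.152). With array quality weights the ribosomal median was -0.062 and the call ended (camera adjusted p = 0.0578). Of 13 mitochondrially encoded genes 0 passed, also over the list alone, with a median of -0.44, -0.44 for mt-Co3 and -0.68 for mt-Atp6 (camera adjusted p = 0.00449, adjusted p = 0.528 with an estimated correlation, fry adjusted p = 0.189). This call ended with the lung level as a covariate (camera adjusted p = 0.617) and with the lung set as a batch term (0.0582), and with quantile normalization the median turned to 0.104 (0.855).

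The other lists did not pass camera with the main settings. Of 20 glycolysis genes 1, Pfkp, was higher and 1, the glucose transporter gene Slc2a1 (-0.67), was lower (median -0.12, camera adjusted p = 0.323). Of 23 cholesterol synthesis genes 1 was higher and 1, Msmo1 (-0.48), was lower (median -0.12, camera adjusted p = 0.17). For both lists the counts adjusted over the list alone were the same, 1 and 1. Of 21 genes of the REST complex and neuronal chromatin 1, Smarca2 (0.52), was higher and 1, Hdac1 (-0.38), was lower, and 5 and 2 adjusted over the list alone (median 0.06, camera adjusted p = 0.447). Of 28 cell cycle, 27 p53 and apoptosis, 18 heat shock and 34 oxidative phosphorylation genes 0 passed, also adjusted over the list alone. Their medians were 0.04, -0.15, -0.07 and -0.13 with camera adjusted p-values of 0.801, 0.222, 0.399 and 0.0502. The oxidative phosphorylation, glycolysis and cholesterol lists passed, towards lower, with the lung level as a covariate (camera adjusted p = 0.000503, 0.00123 and 0.0321) and without control AAV library 3 (0.00514, 0.0363 and 0.0363). Oxidative phosphorylation also passed without miR-9-3p AAV library 2 (0.0488) or 3 (0.0199) and under 7 other alternatives, among them no filter (0.00576) and the lung set as a batch term (0.00397), and the cholesterol list with no filter (0.0458). By fry the adjusted p-values of these 3 lists were 0.347, 0.683 and 0.279. The values were -0.49 for Ccnb2 and 0.36 for Ccna2, -0.65 for Sesn2, 0.28 for Hsph1 and -0.76 for Bag3, and -0.24 for Ndufv2.

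Bdnf, which encodes brain-derived neurotrophic factor, was examined because the study is known to ask about miR-9-3p, synapses and this factor. Bdnf (ENSMUSG00000048482, chromosome 2, 109674700 to 109727007 in mm10) stood at 3.74 ± 0.622 FPKM in control AAV and 2.04 ± 0.369 FPKM in miR-9-3p AAV (SD, n = 3), on 301, 460 and 450 reads against 258, 214 and 177 reads. The values of the groups did not overlap. The log2 fold change of -0.64 (SE 0.15) had a limma adjusted p of 0.0553 over all genes tested, which did not pass, and of 0.0239 adjusted over the list alone. That list holds 6 reported miR-9-3p targets, of which 0 passed over all genes tested and 1, Bdnf, was lower adjusted over the list alone. The other values were -0.44 for Itgb1, -0.07 for Dlg1, 0.12 for Dmd, -0.01 for Rcor1 and -0.07 for Actl6a, with limma adjusted p-values from 0.283 to 0.948. The list had a median of -0.07 and a camera adjusted p of 0.342. The longest annotated 3′ UTR of Bdnf, of 2855 bases, held 3 matches to the miR-9-3p seed and 0 of the 8-base kind. Bdnf passed under 5 of the alternatives, with array quality weights, without the library of each group with the highest lung level, with the lung set as a batch term, with the GC trend removed and with voom on recovered reads. Its adjusted p over the alternatives ran from 0.00136 to 0.268, with the lung level as a covariate its log2 fold change was -0.437 (limma adjusted p = 0.0677), and within the 2 lung sets its log2 differences were -0.58 and -0.50.

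Mature miR-9-3p was not measured by these libraries. Of the 3 mouse genes that encode its hairpin, Mir9-1 (chromosome 3, 88215598 to 88215686) and Mir9-2 (chromosome 13, 83738814 to 83738885) were listed at 0 in each library. Mir9-3 (chromosome 7, 79505264 to 79505353) was listed at 0, 0.619 and 0 FPKM in control AAV and 0, 1.31 and 1.97 FPKM in miR-9-3p AAV. Like mt-Ta, these hairpin genes are short and not well measured by such libraries, so their values cannot show a difference between the groups. Mir9-2 lies in an exon of the long noncoding RNA gene C130071C03Rik (chromosome 13, 83721381 to 83884194). C130071C03Rik rose from 20.1 ± 1.41 to 38.5 ± 1.79 FPKM (SD, n = 3; log2 fold change 0.91, limma adjusted p = 0.017). Mir9-3hg, the host of Mir9-3, stood at 14.1, 13.2 and 11.98 FPKM in control AAV and 11.4, 11.5 and 11.7 FPKM in miR-9-3p AAV and did not pass. Of these host genes 1 was higher and 0 lower, also adjusted over the list alone, and 2 genes were too few for a set test.

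Genes with 3′ UTR matches to the seed of miR-9-3p did not have lower values in miR-9-3p AAV. Among 12194 tested genes with an annotated 3′ UTR, the 2498 with a match (AGCTTTA, or GCTTTAA) had a median log2 fold change of 0.07 and the 9696 without one of -0.06. Genes with a match had longer 3′ UTRs (median 2602.5 against 1000 bases). In a linear model with UTR length and A+T share, a match had a coefficient of 0.0281 (log2). The central 95% of 1000 control heptamers of similar frequency ran from -0.0025 to 0.0344, and the two-sided p of the rank was 0.174 (one-sided towards lower, 0.914). Matches stood in 13.2% of the genes called lower, 42.5% of those called higher and 20.5% of all 12194. Matches to the other strand of the hairpin, miR-9-5p (ACCAAAG, or CCAAAGA), stood in 2850 genes. The median log2 fold change of these genes was 0.03, against -0.05 for genes without a match. With UTR length and A+T share in the model, a miR-9-5p match had a coefficient of -0.0175. This was below the central 95% of its control heptamers (-0.0031 to 0.0357; two-sided p of 0.006). It was 0.0041 without control AAV library 3 (two-sided p of 0.14), 0.0218 with the lung level as a covariate (0.701) and 0.0894 without UTR length and A+T share in the model (0.154). Genes are not replicates, so these ranks describe how these libraries differ.

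**Figure D4:**
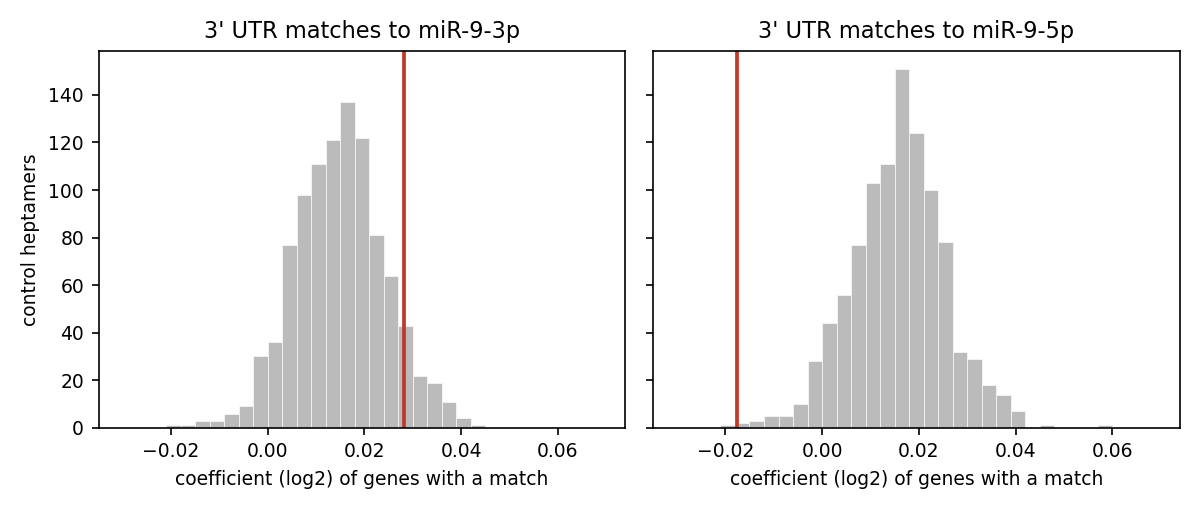
Coefficients (log2, x axis) of 1000 control heptamers in the linear model of 3′ UTR matches (grey; the y axis counts heptamers), for miR-9-3p at left and miR-9-5p at right. The red line is the seed match itself, at 0.0281 within the control heptamers for miR-9-3p and at -0.0175 at their lower end for miR-9-5p.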

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

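The covariate, lung, exon length, GC and voom alternatives and the control heptamers of the seed's own bases were chosen after seeing the data; the others were planned. The counts of genes higher and lower, 554 and 341, moved by over 1.5 times to 109 and 67 with no filter (32968 genes tested), 3183 and 3262 with array quality weights, 1754 and 2309 with the lung level as a covariate, 1410 and 1243 with the lung set as a batch term, 278 and 209 with the exon length trend removed, 1275 and 1035 with the GC trend removed, and 44 and 39 at an absolute log2 fold change of at least 1. Without the library of each group with the highest lung level (control AAV 3 and miR-9-3p AAV 1), the lower count was 885 and the higher 792. Leaving out 1 library gave 0 to 460 higher and 0 to 272 lower; the counts were 0 for each library but control AAV 3. Fewer samples alone do not account for this, since the 4 libraries without the highest lung level gave 792 and 885. Array weights, the covariate and leaving out the highest lung libraries moved the share of calls that were higher from 61.9% to 49.4%, 43.2% and 47.2%. The causes were not tested.

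At an estimated correlation no list passed camera, with a lowest adjusted p of 0.124 (unfolded protein and ATF4 response). At the preset correlation 18 lists passed, 10 with the lung level as a covariate and 13 to 21 under the other alternatives. With that covariate the microglia and inflammatory medians turned to 0.105 and 0.043 and the vesicle and cytoskeleton medians to -0.043 and -0.116, and the camera direction of the endothelial list reversed, at a median of -0.019. Medians of lists that passed in neither fit turned too, from -0.891 to 0.501 for blood cells, -0.069 to 0.041 for reported targets and 0.058 to -0.085 for the REST complex. The mitochondrially encoded median turned to 0.104 with quantile normalization. Bdnf, at -0.64, passed with array weights (-0.77), without the highest lung library of each group (-0.67), with the lung set as a batch term (-0.54), with the GC trend removed (-0.69) and with voom (-0.88); the cause was not tested. Its value with the lung level as a covariate was -0.437 (limma adjusted p = 0.0677), and leaving out 1 library gave -0.75 to -0.55. The miR-9-3p seed coefficient kept its sign and did not pass under any alternative run. The miR-9-5p coefficient turned to 0.0218 with the lung level as a covariate and 0.0894 without covariates, and ran from -0.03 to 0.0041 when 1 library was left out, the highest without control AAV 3; the cause was not tested. Of the single genes followed, 25 no longer passed with the exon length trend removed, 42 with no filter, 10 with quantile normalization, 8 or fewer under each other alternative on all libraries without a block, and 13 (control AAV 3) to 67 when 1 library was left out.

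The replicate numbers showed no pairing of the samples. Deviations from the group means correlated at -0.649, 0.111 and -0.535 for numbers 1, 2 and 3, and not every library correlated best with its own number. The highest correlation, 0.621, was between control AAV library 3 and miR-9-3p AAV library 1, which had the most lung RNA in their groups. Lung RNA can shape these correlations, so they cannot exclude a pairing by culture. With the replicate block limma called 0 genes higher and 0 lower, with 2213 at an unadjusted p under 0.05, and 69 of the single genes followed no longer passed. DESeq2 was planned only for counts and was not run. Depth of 16001205 to 17936453 reads limits genes near 1 FPKM, and the test found 19% of simulated 1.5-fold changes.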

Other observations

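The tests of lung RNA amount, of regulation by miR-9-3p, of a single lung source, of less lung RNA in both sets, of dilution, of exon length, of astrocyte share and of the miR-9-5p explanations were chosen after the result was seen; those of the 2 sets, UTR composition and other splits were written before. Lung lists held 55 measured genes and took 2%, 3.02% and 9.53% of the FPKM sum in control AAV libraries 1, 2 and 3 and 3.27%, 1.16% and 0.8% in miR-9-3p AAV libraries 1, 2 and 3. Beside the airway and surfactant genes they included Ager of alveolar type 1 cells (246 FPKM in control AAV library 3, 20.8 in miR-9-3p AAV library 3), the alveolar macrophage gene Chil3 (86.8 and 9.14) and Myl7, a gene of atrial heart muscle (23.8 and 0.5). The airway genes Reg3g and Tff2 followed Bpifa1. They stood at 13.0 and 11.3 FPKM in control AAV library 3 and were listed at 0 in miR-9-3p AAV libraries 2 and 3.

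The lung transcripts have 2 readings tested here, RNA of lung tissue in the libraries or regulation by the vector. For 20 genes of the other lung lists with a mean of at least 10 FPKM, the median R squared on the alveolar type 2 level was 0.979, consistent with lung RNA mixed in at different amounts, although genes such as Fabp5 that neural cells also express did not follow it. Regulation by miR-9-3p is argued against by a range of 2.175 (log2) within control AAV, wider than the group difference of -1.495, and a single source since the ratio of Bpifa1 to Scgb1a1 differed by 151.1 times with a floor of 3 reads per library. The 2 resulting sets do not account for the whole group effect, since the differences within the sets, which share no library, correlated across genes at 0.671, but the lung level was lower in miR-9-3p AAV in both (by 0.877 and 1.147, log2), which can add to this. Control AAV library 2 and miR-9-3p AAV library 1 differed by 0.016 in lung level, and their difference correlated at 0.592 with that of the other set (0.21 and 0.019 with those between the other 2 control and the other 2 miR-9-3p libraries), against lung amount as the whole cause; how the lung RNA entered stays open.

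The lists of voltage-gated channels, glutamate receptors and postsynaptic scaffolds passed camera towards higher at a preset correlation. At an estimated correlation none of them passed (camera adjusted p = 0.275, 0.297 and 0.357). For the calls at the preset correlation a candidate explanation is a change in the neurons themselves, which was not tested apart from the explanations here. With the lung level as a covariate the channel list kept its call at a median of 0.353 (SE over members, which are not independent, 0.091; 0.371 before), which argues against dilution by lung RNA as its whole cause. The postsynaptic median fell from 0.302 (SE 0.055) to 0.087 (SE 0.094), as dilution needs. The glutamate receptor call ended at a median of 0.241 (SE 0.13), against 0.315 (SE 0.071) before. Whether the lower median or the wider spread ended that call was not tested, so dilution stays open for both lists. With the exon length trend removed the medians were 0.239, 0.281 and 0.201 (SE 0.058, 0.064 and 0.049) and the 3 lists passed, so length accounts for part at most. The log2 fold changes of 17 abundant astrocyte markers ran from -1.55 to 0.21, with an SD of 3.18 times their median standard error. Markers that other cells also express can spread in this way when the astrocyte share falls. A lower astrocyte share alone therefore stays open, as does a change within astrocytes together with their share.

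Genes with miR-9-3p matches were not lower. Their small positive coefficient may reflect UTR composition, since 15.75% of heptamers rearranged from the same bases gave one as high. Within the lung sets the miR-9-3p coefficient was 0.0276 in that of control AAV libraries 2 and 3 (control median 0.0184, one-sided p of the rank towards higher 0.153). It was 0.0409 in that of control AAV library 1 (control median 0.0195, one-sided p of the rank towards higher 0.025). The coefficient of miR-9-5p matches, with UTR length and A+T share in the model, was lower than those of control heptamers. Without this adjustment genes with a match were not lower (median 0.03 against -0.05). A hypothesis is that the vector's hairpin also gave an active 5p strand. In the lung set of control AAV libraries 2 and 3 and miR-9-3p AAV library 1 the coefficient was -0.01 (control median 0.0187, one-sided p of the rank 0.006). In the other lung set it was -0.0003 (control median 0.0206, one-sided p of the rank 0.037). These sets make up the libraries in which the shift was seen, so they do not test it anew. Of 12918 heptamers found in at least 500 genes the lowest coefficient, -0.0366, was that of the match to miR-124 (GTGCCTT). The vector does not carry this neuronal microRNA. Without control AAV library 3 the miR-124 coefficient was -0.0054 at rank 230. It was -0.0352 at rank 5 in the set of control AAV libraries 2 and 3 and miR-9-3p AAV library 1. In the set of control AAV library 1 and miR-9-3p AAV libraries 2 and 3 it was -0.007 at rank 182. The miR-9-5p match ranked 44 over all libraries, so a shift of the RNA towards neurons may give the same pattern. Which of them holds cannot be told apart here, because both shifts vanished with the lung level as a covariate (miR-124 coefficient 0.019, one-sided p of 0.289) and microRNAs were not measured.

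The 6 libraries can be divided into 2 groups of 3 in 10 ways. For genes higher and for genes lower 1 of the 10, the real one, gave as many calls, 554 and 341, and the highest of the others gave 0. With 10 splits the share cannot fall under 0.05.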
